A study of Mus musculus with 10 samples.

How the data were processed

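RNA of the left ventricle of 10 male C57BL/6J mice aged 6 months had been frozen, extracted with Trizol and sequenced from TruSeq libraries by the submitters. Per the submitters' processing notes, reads were converted with bcl2fastq 1.8.4, trimmed with Trim Galore 0.4.0, aligned to mouse mm10 (GRCm38) with Novoalign, handled with SAMtools and tested with DESeq2 1.18.1. The read counter, its annotation and the strand it counted are not given in the sources used here. The deposited table by the authors holds, for 21222 genes, a count per library (whole numbers), and per the file headers a signal (baseMean, the mean of normalized counts), a log2 fold change with its standard error, a score (stat, the Wald statistic) and a p-value with its adjusted form, for TG against NTG. All columns of per-sample values were used. Own DESeq2 1.42.0 on the same counts differed from the authors' deposited log2 fold changes by at most 0.000557.

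Gene symbols came from the table. Of the 21222 genes 1324 had no symbol (0.777% of all counts), 21 symbols turned into dates by a spreadsheet were restored from the reference, and 19872 identifiers were matched to GRCm38 coordinates. Total counts were 7076319 to 10896535 per library, 18113 to 18979 genes had a count in a library, and the 10 genes with the most counts held 11.7 to 16.0% of a library. A fold against a group without counts was computed against 3 counts over the whole group and is a lower bound. A fold with 1 to 3 counts on the lower side has a 95% exact interval that covers counting error only.

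The libraries were grouped by their labels into NTG (4), TGL (3) and TGH (3). TG (6) joins the lines. Gene tests used edgeR 4.0.16 with filterByExpr by group as low-count filter, TMM scaling (factors 0.94 to 1.08) and the quasi-likelihood F test. The Benjamini-Hochberg method adjusted p over all tested genes of a comparison, with 0.05 as threshold. TG against NTG was fitted with 2 groups, the other comparisons with 3 groups in 1 fit. Standard errors (SE) of log2 fold changes are the fold change over the square root of F. The standard deviation (SD) of CPM is between libraries, and CPM are counts scaled to TMM-adjusted library size in the usual unit of edgeR's cpm function. The biological coefficient of variation was 17.1% with 2 groups and 13.9% with 3. Nfe2l2 was tested alone with a two-sided exact permutation test of mean log2 CPM.

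Before the data were examined, the comparisons, the alternatives, 40 gene lists written from general knowledge and the rule for naming genes were fixed. The rule names Nfe2l2 and Keap1 always. In TG against NTG it names the 12 genes with the largest rise and the 12 with the largest fall in log2 fold change among called genes with a mean of at least 1 CPM over all libraries, every TG library beyond every NTG library and an official symbol (no Gm numbers, Rik clones, predicted loci or pseudogenes). In the other comparisons it names 5 rises and 5 falls by the same rule within the libraries compared. For each list described it names up to 4 members by smallest adjusted p, and members needed to say that a group did not move, such as Hmox1, Nppb and Myh7. Lists were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over the 38 lists with at least 3 measured members. Lymphocyte and adipocyte markers were too short to test. Alternatives were an estimated correlation and fry of limma. The tests of these lists in TGL against NTG and of TGH against NTG were added after the data were seen. "Adjusted over the list alone" means Benjamini-Hochberg over the members of a list.

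Other alternatives were DESeq2, RLE size factors, no low-count filter, at least 1 CPM by unadjusted totals in at least 4 libraries, the replicate number as a block, leaving out each library in turn, 2 groups in place of 3 and 3 in place of 2, other thresholds, and controls split between the lines. Leaving out NTG 2 with TGL 2, and the heat shock list's mean as a covariate, were chosen after seeing the data. Sharing of reads between genes was judged by the percentage of 50-base words of a gene's transcripts found in another annotated gene, and genes above 10% are named with their share. Up to 100 splits of the libraries, the real one included, were fitted, and 20 simulations gave the correlation of unchanged groups with shared controls.

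Simulated data took the depth of these libraries and the spread of the 3-group fit. That spread is under the one of the 2-group fit used for TG against NTG. The code was tested on these data with 200 changed genes. With edgeR in TG against NTG it called 56.7% of genes changed 1.5-fold, 83.6% of 2-fold and 93.9% of 4-fold. These were 38, 56 and 62 right calls, beside 13 false calls among 13957 genes run. For TGL against NTG the percentages were 46.3, 73.1 and 97.0 with 7 false calls of 14060, for TGH against NTG 29.9, 71.6 and 92.4 with 4 of 14051, and for TGH against TGL 25.4, 67.2 and 86.4 with 2 of 14071. DESeq2 made more false calls, 21 in TG against NTG beside 41, 59 and 65 right ones. In the other comparisons, in the same order, it made 24, 18 and 12. A raised list was called by camera in all 4 comparisons, and of the 37 other lists 0, 0, 0 and 1 were called. The simulated genes varied independently, so these counts do not measure false list calls where members correlate. In the data the estimated correlation was 0.731 for the unfolded protein response and 0.403 for glutathione synthesis in TG against NTG. That 2-group fit keeps the difference between the lines in its spread, so its estimates do not measure variation between mice of a line alone. With 3 groups glutathione synthesis had -0.074 in TGL against NTG and -0.0641 in TGH against NTG. The unfolded protein response had 0.722 in TGL against NTG. Correlations across genes, clusters and library flags were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and R 4.3.3, and figures were drawn with matplotlib 3.10.9.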

Results

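RNA of the left ventricle was sequenced from 10 male C57BL/6J mice aged 6 months. The mice fell into 3 groups: 4 non-transgenic mice (NTG), 3 mice of a line with a low level of a constitutively active Nrf2 transgene in the heart (TGL) and 3 mice of a line with a high level (TGH). Nrf2, encoded by Nfe2l2, is the transcription factor that switches on antioxidant and detoxification genes, and TG stands for both lines together. Whole-number read counts per gene totalled 7893108, 10092841, 8914135 and 9049306 in NTG 0 to NTG 3, 7076319, 7209819 and 7103405 in TGL 0 to TGL 2, and 8168959, 10896535 and 8610470 in TGH 0 to TGH 2. A gene with 3 counts stood at 0.259 to 0.436 CPM (counts scaled to TMM-adjusted library size) depending on the library, which is the limit that a count of 0 allows. Pairs of libraries of a group correlated across genes with r between 0.972 and 0.99 on the log2 CPM scale. Their differences exceeded counting noise 3.06 to 19.5 times (chi-square per degree of freedom), most in pairs with NTG 2, so no 2 libraries were counted as 1. On the leading principal component, which held 54.5% of the variance, NTG libraries lay between -44.4 and -37.6, TGL between -4.26 and 14.8 and TGH between 42.3 and 52, with TGL 2 the TGL library nearest to NTG.

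Nfe2l2 (ENSMUSG00000015839, GRCm38 chromosome 2, 75675513 to 75704641) stood at 164, 145, 88.1 and 121 CPM in the 4 NTG libraries, 156, 128 and 182 CPM in TGL, and 253, 182 and 243 CPM in TGH. A two-sided exact permutation test of TG against NTG gave a 1.47-fold higher mean with p = 0.0667 over 210 splits (adjusted p = 0.1, Benjamini-Hochberg over 3 comparisons), where 0.00476 is the smallest p the design allows. In this transgene check the exact p passed without NTG 0 (p = 0.0476) and without TGL 1 (p = 0.0238). The exact permutation test gave 1.22-fold and p = 0.343 for TGL against NTG (adjusted p = 0.343) and 1.77-fold and p = 0.0571 for TGH against NTG (adjusted p = 0.1), with 0.0286 the smallest p allowed in each. For TGH against TGL, which was not among the comparisons planned for it, the exact permutation test gave 1.45-fold and p = 0.2, and 3 mice against 3 cannot go below 0.1. The transgene may carry only part of the Nfe2l2 sequence or another species' sequence, so these values do not check the labels. Keap1 (ENSMUSG00000003308, chromosome 9, 21229730 to 21239361), whose protein holds Nrf2 in check, rose by 0.58 ± 0.07 (log2 fold change ± SE) in TGH against NTG (edgeR adjusted p = 8.72e-05).

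The comparison of TG with NTG asks which transcripts of the heart differ when active Nrf2 is present. Several genes that make and use glutathione rose. Gclm, which encodes the modifier subunit of the enzyme that starts glutathione synthesis (ENSMUSG00000028124, GRCm38 chromosome 3, 122245557 to 122270732), rose 10.3-fold, from 35.4 ± 7.90 CPM in NTG (SD, n = 4) to 181 ± 21.1 CPM in TGL and 547 ± 36.7 CPM in TGH (SD, n = 3 each). Its log2 fold change in TG was 3.37 ± 0.45 (SE), with an adjusted p of 0.00139 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Glutathione reductase (Gsr, 2.80-fold) and the plasma glutathione peroxidase (Gpx3, 1.64-fold) rose with it. Of the 11 measured genes of glutathione synthesis and reduction, 8 rose and 0 fell, with 8 and 0 when adjusted over the list alone (median log2 fold change 0.71, camera adjusted p = 6.78e-05, adjusted p = 0.417 with an estimated correlation). Among 21 glutathione S-transferases, which couple glutathione to foreign and oxidised compounds, 8 rose and 3 fell, with 8 and 5 when adjusted over the list alone (camera adjusted p = 0.00493, adjusted p = 0.417 with an estimated correlation). Gsta1 (ENSMUSG00000074183, chromosome 9, 78230656 to 78242684) went from 5.06 ± 0.914 CPM (SD, n = 4) to 265 ± 44.9 CPM in TGL and 814 ± 122 CPM in TGH (SD, n = 3 each). Gsta1 shared 90.5% of its 50-base words with another annotated gene and Gsta2 49.8%, so how reads were divided between these neighbours is uncertain. Gsta3 rose 13.3-fold and Gstm2 4.28-fold.

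Several enzymes that remove quinones and carbonyls and that supply NADPH rose as well. Nqo1, the quinone reductase (ENSMUSG00000003849, GRCm38 chromosome 8, 107388225 to 107403206), went from 60.9 ± 7.19 CPM (SD, n = 4) to 114 ± 12.5 CPM in TGL and 154 ± 10.4 CPM in TGH (SD, n = 3 each), 2.20-fold in TG (edgeR adjusted p = 0.00109). The esterase Esd rose 5.62-fold, the carbonyl reductase Cbr3 5.58-fold and the aldo-keto reductase Akr1b8 3.70-fold. In the quinone and carbonyl list 10 of 19 measured genes rose and 1 fell, with 11 and 1 when adjusted over the list alone (camera adjusted p = 6.78e-05, adjusted p = 0.517 with an estimated correlation). Transaldolase (Taldo1, 6.54-fold) and 6-phosphogluconate dehydrogenase (Pgd, 4.05-fold), both of the pentose phosphate pathway, rose among 6 of 13 NADPH genes, with 0 that fell and 7 and 1 when adjusted over the list alone (camera adjusted p = 0.00478, adjusted p = 0.258 with an estimated correlation). Biliverdin reductase B (Blvrb) rose 15.4-fold and ferritin heavy chain (Fth1) 1.35-fold. Haem and iron genes counted 4 that rose of 12 and 0 that fell, with 5 and 1 when adjusted over the list alone (camera adjusted p = 0.0206, adjusted p = 0.417 with an estimated correlation). Hmox1, the haem oxygenase of that list, had a log2 fold change of 0.24 ± 0.43 (SE, edgeR adjusted p = 0.725). With 1 library left out the called members numbered, for NADPH genes 2 (without NTG 1 or NTG 3) to 6.

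Sulfiredoxin (Srxn1, 3.33 on the log2 scale), peroxiredoxin 6 (Prdx6, 4.71-fold) and thioredoxin reductase 1 (Txnrd1, 2.77-fold) rose, while the sestrin Sesn1 fell by 1.08 on the log2 scale. The thioredoxin and peroxiredoxin list counted 5 that rose and 1 that fell of 15, with 6 and 2 when adjusted over the list alone (camera adjusted p = 0.0332, adjusted p = 0.517 with an estimated correlation). Its call was lost without NTG 0 (camera adjusted p = 0.0604) and without NTG 3 (camera adjusted p = 0.0984). Of 10 genes of superoxide and peroxide removal 3 rose, Gpx8, catalase (Cat) and Selenow, and 1 fell, with 3 and 1 when adjusted over the list alone (camera adjusted p = 0.192). Nrf2 and its partners counted 2 that rose and 1 that fell of 10, with 3 and 1 when adjusted over the list alone (camera adjusted p = 0.896). Keap1 was among them at 0.38 ± 0.12 (log2, edgeR adjusted p = 0.0493), a call that ended without NTG 0 (edgeR adjusted p = 0.117), NTG 1 (0.113), NTG 2 (0.0944), NTG 3 (0.0825), TGH 0 (0.0951), TGH 1 (0.0962) or TGH 2 (0.072). It also ended without a filter on low counts (edgeR adjusted p = 0.062). Leaving out 1 library gave called members, for Nrf2 partners 0 (without NTG 0, NTG 1 or TGH 0) to 4.

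**Figure D1:**
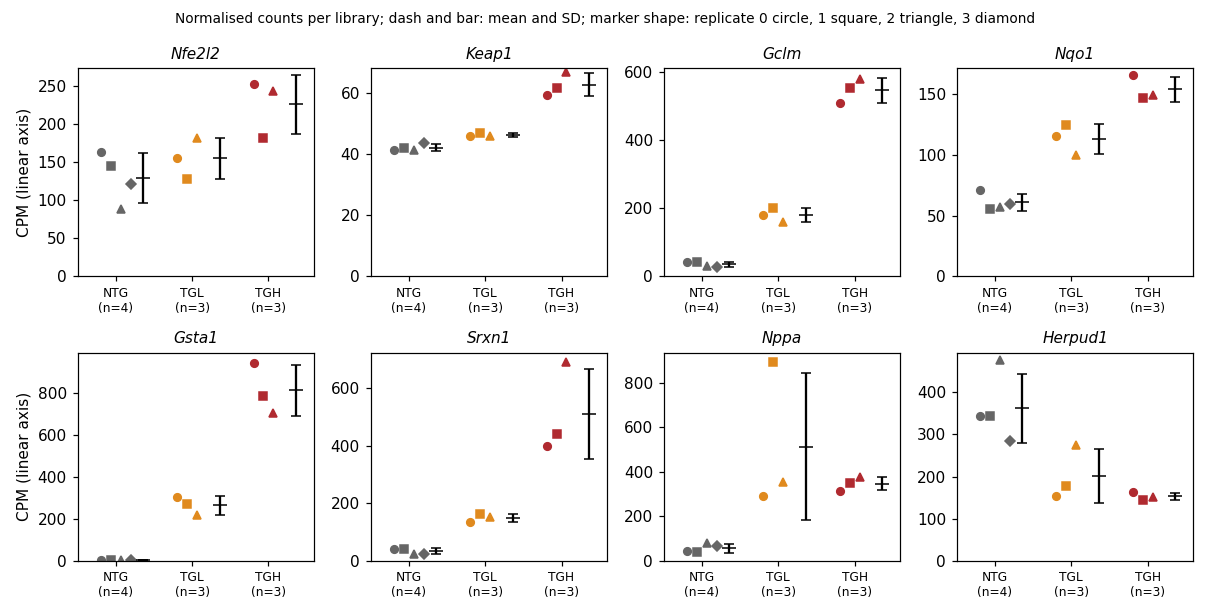
CPM of 8 genes in each of the 10 libraries on linear axes, with a point for each library and, beside each group, its mean and SD. Gclm stood at 35.4 CPM on average in NTG, 181 CPM in TGL and 547 CPM in TGH.

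The furthest rises were of genes at or near 0 counts in NTG. Against a floor of 3 counts over the 4 NTG libraries together, the somatostatin receptor Sstr5 was at least 214-fold higher, neuronal pentraxin Nptx2 at least 214-fold, Brinp3 at least 149-fold, Tekt5 at least 118-fold, Skint7 at least 61.1-fold, Nell2 at least 39.1-fold, Tchhl1 at least 34.8-fold, the GABA receptor subunit Gabra4 at least 33.2-fold and plasminogen (Plg) at least 29.0-fold. Atp1b4 had 1 count in NTG, from NTG 2, and 636 in TG, a ratio of 428 with a 95% exact interval of 76.6 to 16950 that covers counting error only. Gpr83 rose from 0.136 to 30.6 CPM (7.59, log2, and 8.33 without NTG 1) and Map7d2 from 0.945 to 103 CPM. Among the furthest falls were those of Tmem82 (-2.22), Cox6b2 (-2.20), the melanin enzyme Dct (-2.15), Shisa6 (-2.10), Tmem150c (-2.09), the metalloproteinase inhibitor Timp4 (-1.99), Ifi205 (-1.97), Ly75 (-1.87), Lgals4 (-1.81), Rtn4r (-1.70) and Rnf157 (-1.69), in log2. Shisa6 was not called without NTG 2 (edgeR adjusted p = 0.0586), and Rtn4r was not called without NTG 2 (0.0772) or TGH 0 (0.051). Tmem82 shared 20.3% of its 50-base words with another gene, Ifi205 18.6% and Plg 10.2%, so their values are uncertain.

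Among cardiac stress genes, Nppa, which encodes atrial natriuretic peptide (ENSMUSG00000041616, GRCm38 chromosome 4, 148000722 to 148002079), went from 57.4 ± 20.3 CPM in NTG (SD, n = 4) to 514 ± 330 CPM in TGL and 347 ± 31.0 CPM in TGH (SD, n = 3 each), 7.50-fold in TG (edgeR adjusted p = 0.00123). The nicotinamide riboside kinase Nmrk2 (5.87-fold) and the deubiquitinase Uchl1 (3.94-fold) rose too. Nppa shared 53.4% of its words with another annotated gene, Nmrk2 13.5% and Uchl1 12.6%, which leaves their shares of reads uncertain. Nppb had 0.67 ± 0.54 (log2 ± SE, edgeR adjusted p = 0.404, but 0.00954 without NTG 2, where it stood at 628 CPM) and Myh7, with 20% shared words, -0.07 ± 0.24 (edgeR adjusted p = 0.866). In the hypertrophy and fetal list 4 of 15 rose and 0 fell, with 6 and 1 when adjusted over the list alone (camera adjusted p = 0.0823). The mean of that list in NTG 2, 7.685 log2 CPM, lay within the TG range of 7.193 to 7.881. The other NTG libraries had 6.523 to 6.788. The atrial light chain Myl4 rose 13.3-fold (edgeR adjusted p = 0.000619) and Dkk3 2.59-fold. Atrial markers counted 2 that rose and 1 that fell of 5, the same when adjusted over the list alone (camera adjusted p = 0.0415, adjusted p = 0.417 with an estimated correlation). The atrial call ended without NTG 2 (camera adjusted p = 0.0509), NTG 3 (0.0899), TGL 2 (0.0625) or TGH 2 (0.0565).

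None of 14 adult sarcomere genes rose and 3 fell, Cmya5 (19.5% shared words), Tpm1 and Mylk3, the same when adjusted over the list alone (median log2 fold change -0.29, camera adjusted p = 0.0165, adjusted p = 0.517 with an estimated correlation). The calcium pump Atp2a2 fell by 0.40 and the ryanodine receptor Ryr2 by 0.43 on the log2 scale, while Camk2d (1.76-fold) and calsequestrin (Casq2, 1.36-fold) rose. Calcium handling and ion channel genes counted 5 that rose and 3 that fell of 22, with 5 and 6 when adjusted over the list alone (camera adjusted p = 0.896). TGH 2 had the lowest mean of that list at 7.52 log2 CPM, against 7.62 to 7.67 in the other TG libraries. Called members with 1 library left out were, for sarcomere genes 0 (without NTG 0, NTG 1, TGH 0, TGH 1 or TGH 2) to 4.

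Some genes of mitochondrial fuel use fell. The nuclear receptor Ppara fell by 0.80 on the log2 scale, one of 8 that fell of 24 fatty acid oxidation genes, with 0 that rose and the same counts when adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.517 with an estimated correlation). Without TGH 2, whose list mean was 7.69 log2 CPM against 8.16 to 8.23 in the other TG libraries, the fatty acid call was lost (camera adjusted p = 0.0524). Of 29 oxidative phosphorylation genes 0 rose and 7 fell, Cox7a1 (-0.60, log2) and Ndufv2 (-0.32) among them, with 0 and 9 when adjusted over the list alone (camera adjusted p = 0.00493, adjusted p = 0.517 with an estimated correlation). Only 3 of 13 mitochondrially encoded messages were measured, and 1 of them fell (camera adjusted p = 0.0711). Glycolysis counted 3 that rose, with hexokinase 1 (Hk1, 1.61-fold) and Pfkp (1.66-fold), and 3 that fell, with Pfkfb1 (0.501-fold), of 21 genes, and 4 and 5 when adjusted over the list alone (camera adjusted p = 0.896). Cholesterol synthesis counted 1 that rose and 1 that fell of 14, with 3 and 1 when adjusted over the list alone (camera adjusted p = 0.167). Over fits without 1 library the called members were, for fatty acid oxidation 1 (without NTG 1) to 8 and for oxidative phosphorylation 2 (without NTG 1) to 9. Without 1 library at a time the called members ran, for mitochondrial messages 0 (without NTG 0, NTG 1, NTG 2, TGH 0 or TGH 1) to 1 and for glycolysis 3 (without NTG 0) to 7. When 1 library was left out the called members were, for cholesterol synthesis 0 (without NTG 0, NTG 1, TGH 0, TGH 1 or TGH 2) to 5 (without TGL 2).

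Several genes of protein folding fell. Herpud1, of the degradation of misfolded proteins at the endoplasmic reticulum, fell by 1.03 on the log2 scale (edgeR adjusted p = 0.005), from 362 ± 81.8 CPM in NTG (SD, n = 4) to 202 ± 64.3 CPM in TGL and 153 ± 8.92 CPM in TGH (SD, n = 3 each). The chaperones Canx (-0.55, log2) and Dnajb9 (-0.63) fell as well. Of 18 genes of the unfolded protein response 0 rose and 12 fell, with 0 and 16 when adjusted over the list alone (median -0.66, camera adjusted p = 6.78e-08, adjusted p = 0.517 with an estimated correlation). Heat shock proteins counted 1 that rose, Hspb7 (1.41-fold), and 3 that fell of 16, with 1 and 4 when adjusted over the list alone (median -0.63, camera adjusted p = 0.0135, adjusted p = 0.553 with an estimated correlation). Hspa8 was among them at -0.85 (log2), a call lost without NTG 0 (edgeR adjusted p = 0.0568), and it shared 39.4% of its words with other genes. The heat shock list's mean log2 CPM was 9.01, 8.73, 7.85 and 8.75 in NTG, 7.24, 7.53 and 8.96 in TGL, and 7.21, 7.52 and 8.30 in TGH, so NTG 2 lay low and TGL 2 high in their groups. The unfolded protein response list had 6.79, 6.71, 6.35 and 6.64 in NTG, 5.83, 5.90 and 6.58 in TGL, and 5.69, 5.66 and 6.13 in TGH. The integrated stress response counted 0 that rose and 3 that fell of 18 (camera adjusted p = 0.129). Of 31 proteasome subunits 4 rose and 0 fell (camera adjusted p = 0.419), and autophagy and lysosome counted 3 that rose and 4 that fell of 16, with 4 and 5 when adjusted over the list alone (camera adjusted p = 0.986). Of 6 atrophy ubiquitin ligases 1 rose and 0 fell (camera adjusted p = 0.997). With 1 library left out the called members numbered, for the unfolded protein response 3 (without NTG 0) to 17 and for heat shock proteins 1 (without NTG 0) to 11 (without TGL 2). Leaving out 1 library gave called members, for the integrated stress response 0 (without NTG 1) to 5 (without TGL 2) and for proteasome subunits 1 (without NTG 0 or NTG 1) to 7 (without TGL 2). Called members with 1 library left out were, for autophagy 3 (without NTG 1) to 8 and for atrophy ligases 0 (without NTG 0, NTG 1, NTG 2, NTG 3, TGL 1, TGH 0, TGH 1 or TGH 2) to 1.

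**Figure D2:**
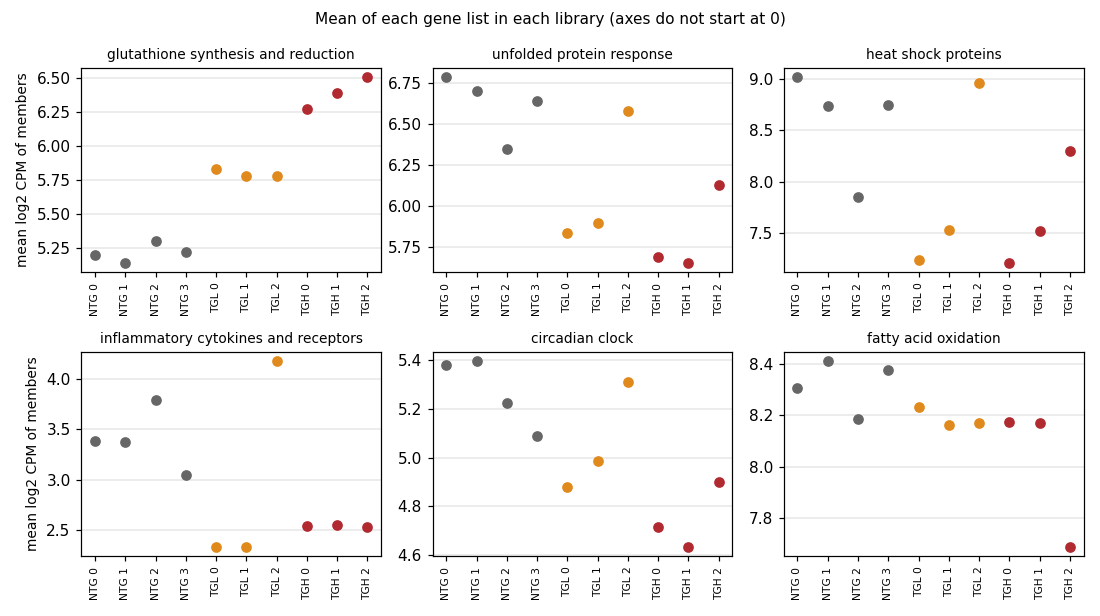
Mean log2 CPM of the members of 6 gene lists in each of the 10 libraries, with a point for each library and axes that do not start at 0. In the heat shock panel NTG 2 stands at 7.85 below the other NTG libraries and TGL 2 at 8.96 above the other TGL libraries.

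Markers of other cell types moved in different directions. Fibroblast markers counted 6 that rose and 0 that fell of 10, with 7 and 0 when adjusted over the list alone (camera adjusted p = 0.00102, adjusted p = 0.417 with an estimated correlation), led by lumican (Lum, 2.22-fold) and Pi16 (1.81-fold). Extracellular matrix genes, which share Lum, Dcn and Col1a1 with those markers, counted 9 that rose and 1 that fell, the crosslinking enzyme Lox (-1.11, log2), of 24, with 10 and 3 when adjusted over the list alone (camera adjusted p = 0.0243, adjusted p = 0.517 with an estimated correlation). The matrix call ended without NTG 0 (camera adjusted p = 0.0705), NTG 1 (0.0907) or TGH 2 (0.0524). Endothelial markers counted 0 that rose and 4 that fell of 10, Tie1 (-0.39, log2), Flt1, Pecam1 and Esam, the same when adjusted over the list alone (camera adjusted p = 0.0165, adjusted p = 0.517 with an estimated correlation). The fibroblast mean of NTG 2 was 6.54 log2 CPM, against 6.13 to 6.28 in the other NTG libraries. The other markers were not called by camera: smooth muscle with 1 that rose and 1 that fell of 9 (adjusted p = 0.22), macrophage with 1 and 0 of 10 (adjusted p = 0.16), and Schwann cell and neuron with 2 and 0 of 5 (adjusted p = 0.129), Sox10 (2.35-fold) included. Erythroid (5 measured, camera adjusted p = 0.467) and skeletal muscle markers (3 measured, camera adjusted p = 0.896) had 0 called members with edgeR, 0 with DESeq2 and 0 at an unadjusted edgeR p under 0.05. Lymphocyte and adipocyte markers had too few measured members to test. Over fits without 1 library the called members were, for fibroblast markers 2 (without NTG 0 or NTG 1) to 7 and for matrix genes 2 (without NTG 0 or NTG 1) to 11. Without 1 library at a time the called members ran, for endothelial markers 1 (without NTG 0 or NTG 1) to 4 and for smooth muscle 1 (without NTG 0, NTG 1, TGH 1 or TGH 2) to 3. When 1 library was left out the called members were, for macrophage 0 (without NTG 0 or NTG 1) to 3 (without TGL 2) and for Schwann cell markers 1 (without NTG 0, NTG 1, NTG 2, TGL 1, TGL 2, TGH 0 or TGH 2) to 2.

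Cell cycle genes, of 11 measured, counted 2 that rose, Ccnb2 and Ccna2 (11.4% shared words), and 0 that fell, with 7 and 0 when adjusted over the list alone (median 0.74, camera adjusted p = 0.00535, adjusted p = 0.517 with an estimated correlation). Inflammatory cytokines and receptors counted 0 that rose and 2 that fell of 10, with 0 and 3 when adjusted over the list alone (camera adjusted p = 0.0192, adjusted p = 0.517 with an estimated correlation). The inflammatory list was not called without NTG 2 (camera adjusted p = 0.0955), and TGL 2 had a mean of 4.18 log2 CPM against 2.33 to 2.55 in the other TG libraries. Circadian clock genes counted 0 that rose and 2 that fell of 17, the same when adjusted over the list alone (camera adjusted p = 0.0332, adjusted p = 0.517 with an estimated correlation). The clock call ended without NTG 0 (camera adjusted p = 0.0626), NTG 1 (0.0683), TGH 1 (0.0503) or TGH 2 (0.0524). Interferon response genes counted 0 and 2 of 17 (camera adjusted p = 0.131), p53 targets 0 and 2 of 12 with Sesn1 (camera adjusted p = 0.509), and microRNA machinery 1 and 1 of 14 (camera adjusted p = 0.503). Immediate early genes had 0 called of 15 with edgeR, 2 with DESeq2 and 6 lower at an unadjusted edgeR p under 0.05 (camera adjusted p = 0.0559), with TGL 2 at a mean of 5.01 log2 CPM and TGL 0 at 3.41. The median, the mean and the camera direction differed in sign for Nrf2 partners, calcium handling, autophagy, atrophy ligases and smooth muscle markers, all of them not called. With 1 library left out the called members numbered, for cell cycle genes 0 (without NTG 0, NTG 1, NTG 3, TGL 1, TGH 0 or TGH 1) to 6 (without TGL 2) and for inflammatory genes 0 (without NTG 0, NTG 1, NTG 2, TGL 0, TGL 1, TGH 0 or TGH 1) to 9 (without TGL 2). Leaving out 1 library gave called members, for clock genes 0 (without NTG 0, NTG 1, TGL 1, TGH 0 or TGH 1) to 6 (without TGL 2) and for interferon genes 1 (without NTG 0, NTG 1, NTG 3 or TGH 1) to 4 (without TGH 0). Called members with 1 library left out were, for p53 targets 1 (without NTG 0, NTG 1, NTG 3 or TGH 1) to 2 and for microRNA machinery 0 (without NTG 0 or NTG 1) to 4 (without TGL 2). Over fits without 1 library the called members were, for immediate early genes 0 to 3 (without TGL 2).

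In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2477 of 14265 tested genes in TG against NTG, of which 1332 rose and 1145 fell, 505 and 161 of them at least 2-fold. Over all tested genes, called or not, the TG and NTG libraries did not overlap in 2008 (14.1%), which chance gives for 0.952%. The called genes held 1681 of these. Camera with a preset correlation called 18 of 38 lists, 10 up and 8 down, against 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 13 with fry. The 2-group fit keeps the difference between the lines in its spread, which enters the estimated correlation. The authors' deposited table, made with DESeq2, has 2900 genes with an adjusted p under 0.05, of which 2411 were among the 2477. By direction, 718 rose and 464 fell without NTG 1, 746 and 479 without NTG 0, and 1761 and 1790 without TGL 2. The count of genes was 1182 without NTG 1, 1225 without NTG 0, 1616 without TGH 0 and 1592 without TGH 1, and 3727 when both lines were fitted as groups of their own. With the heat shock list's mean as a covariate, an alternative added after the data were seen that runs along with the groups, it was 552, and without NTG 2 and TGL 2, also added later, 3218.

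The comparison of TGL with NTG asks what the lower transgene level changes. Gsta1 rose 52.1-fold, Gsta2 42.5-fold and Gsta3 5.40-fold, the first pair with shared reads. Gclm rose 5.11-fold (log2 2.35 ± 0.15, edgeR adjusted p = 2.33e-06), Blvrb 7.29-fold, Srxn1 4.54-fold, Taldo1 3.58-fold, Esd 3.42-fold and Nqo1 1.87-fold. Nppa, with 53.4% shared words, rose by 3.16 on the log2 scale (edgeR adjusted p = 0.000336) and by 2.50 without TGL 1, and Lum rose 2.02-fold. The carboxylesterase Ces1d fell by 0.99 on the log2 scale, Poln by 3.51, and the sorting receptor Sorcs2 by 2.72, and Ifi205 fell to 0.165-fold. Poln and Sorcs2 start on chromosome 5 at 34007179 and 36017180. Ifi205 lies near Ifi202b on chromosome 1, a gene on in some libraries of a group and off in others. Whether the transgene level or a variant at these places set the falls of Poln, Sorcs2 and Ifi205 was not tested. Against the floor of 3 counts over NTG, Sstr5 was at least 76.0-fold higher, Nptx2 at least 66.5-fold, Brinp3 at least 64.3-fold, Tekt5 at least 51.0-fold and Tchhl1 at least 40.4-fold.

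Of 11 glutathione synthesis genes 5 rose and 0 fell in TGL, with 8 and 0 when adjusted over the list alone (camera adjusted p = 3.49e-06, adjusted p = 0.0259 with an estimated correlation). NADPH genes counted 3 that rose of 13, Taldo1, Pgd (2.72-fold) and the isocitrate dehydrogenase Idh1 (2.15-fold), and 0 that fell, with 6 and 0 when adjusted over the list alone (camera adjusted p = 2.76e-08, adjusted p = 0.0259 with an estimated correlation). Glutathione S-transferases counted 7 and 2 of 21, with 8 and 4 when adjusted over the list alone (camera adjusted p = 1.44e-12, adjusted p = 0.0516 with an estimated correlation). Quinone and carbonyl genes counted 6 and 1 of 19, with 8 and 1 when adjusted over the list alone (camera adjusted p = 6.47e-05, adjusted p = 0.337 with an estimated correlation). Haem and iron genes counted 2 and 0 of 12, with 3 and 0 when adjusted over the list alone (camera adjusted p = 0.00106, adjusted p = 0.146 with an estimated correlation). Fibroblast markers counted 2 and 0 of 10, with 6 and 0 when adjusted over the list alone (camera adjusted p = 0.0066, adjusted p = 0.52 with an estimated correlation). Without 1 library at a time the called members ran, for glutathione synthesis 3 (without NTG 0, TGL 0 or TGL 1) to 7 and for haem and iron genes 1 (without NTG 0, NTG 1, NTG 3, TGL 0, TGL 1 or TGH 1) to 3. When 1 library was left out the called members were, for fibroblast markers 1 (without NTG 0, NTG 1, TGL 0 or TGL 1) to 3.

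The lists called as lower in TGL were the unfolded protein response, with 0 that rose and 3 that fell of 18 and 0 and 11 when adjusted over the list alone (median -0.49, camera adjusted p = 1.63e-05, adjusted p = 0.624 with an estimated correlation), and 2 others. Interferon response genes counted 0 and 1 of 17, with 0 and 3 when adjusted over the list alone (camera adjusted p = 0.00221, adjusted p = 0.624 with an estimated correlation). Oxidative phosphorylation counted 0 and 2 of 29, with 0 and 7 when adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.624 with an estimated correlation), a call lost without TGL 2 (camera adjusted p = 0.0513). Herpud1 had -0.84 (log2) in TGL, and its call ended without NTG 0 (edgeR adjusted p = 0.0597), NTG 1 (0.0606), TGL 0 (0.137) or TGL 1 (0.131). TGL 2 stood apart in the unfolded protein response list, at 6.58 log2 CPM against 5.83 and 5.90 in the other TGL libraries. Zfp982 (-4.64, log2, with 11.9% shared words, and -6.22 without TGL 2) was not called without TGL 0 (edgeR adjusted p = 0.085) or TGL 1 (0.0814), nor Fbxo44 (-4.17) without TGL 0 (0.0613) or TGL 1 (0.0661). In TGH 0 and TGH 2 Zfp982 stood at 5.73 and 3.99 CPM and Fbxo44 at 9 and 8.2, within their NTG ranges, but both stood at 0.518 in TGH 1. Both genes start on chromosome 4 at 147492417 and 148152800, and Nppa lies between them. Whether the transgene level or a variant at this place set the shared pattern of Zfp982 and Fbxo44 was not tested. Nor was it tested whether such a variant bears on Nppa. The median, the mean and the camera direction differed in sign for calcium handling, glycolysis, smooth muscle and macrophage markers, none of them called. With 1 library left out the called members numbered, for the unfolded protein response 0 (without NTG 0, NTG 1, TGL 0 or TGL 1) to 12 (without TGL 2) and for interferon genes 0 (without NTG 0, NTG 1, TGL 0 or TGH 1) to 4 (without TGH 0). Leaving out 1 library gave called members, for oxidative phosphorylation 0 (without TGL 0) to 3.

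In TGL against NTG, edgeR's quasi-likelihood test called 913 of 14511 genes, 602 that rose and 311 that fell, 297 and 47 of them at least 2-fold. Over all tested genes, called or not, the libraries of the groups did not overlap in 2932 (20.2%), which chance gives for 5.71%, with 897 of these called. Camera called 9 of 38 lists, 6 up and 3 down, against 2 with an estimated correlation and 11 with fry. The count of genes was 562 without NTG 0, 554 without NTG 1, 457 without TGL 0, 486 without TGL 1 and 1399 without TGL 2. The split by direction went with it: 373 rose and 84 fell without TGL 0, and 372 and 114 without TGL 1. The counts were 418 and 144 without NTG 0, 411 and 143 without NTG 1, and 734 and 665 without TGL 2 (81.6% to 52.5% that rose). Without NTG 2 and TGL 2 together, a choice made after the data were seen, 1666 genes and 19 lists were called, and 15 and 14 lists without NTG 2 or TGL 2 alone.

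The comparison of TGH with NTG asks the same of the higher level. Gclm rose 15.5-fold (log2 3.95 ± 0.15, edgeR adjusted p = 8.83e-09), Srxn1 15.5-fold, Blvrb 23.5-fold, Gsta3 21.1-fold, Taldo1 9.48-fold, the reductase Ptgr1 8.86-fold, Pgd 5.35-fold and Nqo1 2.53-fold. Gsta1 (160-fold) and Gsta2 (146-fold) had shared reads. Mafg, a partner of Nrf2 on DNA, rose 2.35-fold. Nmrk2 rose 9.36-fold, Nppa 6.04-fold and Uchl1 5.83-fold. Nptx2 was at least 321-fold higher than the NTG floor, Sstr5 at least 315-fold, Brinp3 at least 211-fold, Tekt5 at least 167-fold and Skint7 at least 83.6-fold. Complement C1s1 had 2 counts in TGH and 935 in NTG, 401 times lower with a 95% exact interval of 111 to 3316, and C1s2 had 2 and 177 counts, 75.9 times lower with 20.7 to 632. C1s1 shared 35.1% of its words with another gene and C1s2 26.9%, so both are uncertain. Both lie on chromosome 6 and were also off in TGL 0 (0.138 and 0 CPM), but on in TGL 1 (15 and 3.4) and TGL 2 (11.8 and 2.18). Their shared on or off pattern thus did not follow the lines alone, and its cause was not tested. In edgeR C1s1 had -8.37 (log2), and -7.75 without TGH 1. Tac1 had 3 and 72 counts, 20.6 times lower with 6.77 to 102, while Lgi1, with 12.9% shared words, fell by 4.18, Dct by 4.13 and Ces1d by 2.54 on the log2 scale. Lgi1 had -3.58 without TGH 1 and -7.30 without TGH 2, and Tac1 had -4.17 in edgeR, -3.53 without TGH 1 and -5.02 without TGH 2.

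Of 11 glutathione synthesis genes 9 rose and 0 fell in TGH, the same when adjusted over the list alone (camera adjusted p = 2.16e-09, adjusted p = 0.00991 with an estimated correlation). Glutathione S-transferases counted 8 and 3 of 21, with 9 and 4 when adjusted over the list alone (camera adjusted p = 1.28e-10, adjusted p = 0.074 with an estimated correlation). Quinone and carbonyl genes counted 12 and 1 of 19, the same when adjusted over the list alone (camera adjusted p = 5.13e-08, adjusted p = 0.1 with an estimated correlation). Thioredoxin genes, Txnrd1 (3.86-fold) included, counted 9 and 2 of 15, the same over the list alone (camera adjusted p = 0.000533, adjusted p = 0.144 with an estimated correlation). NADPH genes counted 5 and 1 of 13 (camera adjusted p = 5.26e-05, adjusted p = 0.074 with an estimated correlation) and haem and iron genes 5 and 1 of 12 (camera adjusted p = 0.00124, adjusted p = 0.129 with an estimated correlation), both the same when adjusted over the list alone. Fibroblast markers counted 7 and 0 of 10 (camera adjusted p = 0.0216, adjusted p = 0.542 with an estimated correlation) and macrophage markers, with Lyz2 (1.58-fold) and C1qa (1.67-fold), 5 and 0 of 10 (camera adjusted p = 0.0256, adjusted p = 0.639 with an estimated correlation), again the same over the list alone. The macrophage call ended without NTG 3 (camera adjusted p = 0.0589) or TGH 0 (0.0718), and Lyz2 shared 15.4% of its words with another gene.

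Several genes of contraction and oxidative metabolism fell in TGH. Cardiac troponin I (Tnni3) fell by 0.61, the light chains Myl3 and Myl2 by 0.63 and 0.46 on the log2 scale, and Cmya5, with 19.5% shared words, to 0.442-fold, among 10 that fell of 14 sarcomere genes with 1 that rose, and 11 and 1 when adjusted over the list alone (camera adjusted p = 0.000571, adjusted p = 0.0866 with an estimated correlation). The cytochrome oxidase subunits Cox6a2 (-0.81, log2) and Cox8b (-0.84) were among 13 that fell of 29 oxidative phosphorylation genes, with 0 that rose and the same over the list alone (camera adjusted p = 0.00162, adjusted p = 0.542 with an estimated correlation). Hadha (-0.68) and Hadh (-0.50) fell among 13 of 24 fatty acid oxidation genes, with 0 that rose and 14 that fell when adjusted over the list alone (camera adjusted p = 0.0131, adjusted p = 0.705 with an estimated correlation). The fatty acid call was lost without TGH 2 (camera adjusted p = 0.161). The 3 measured mitochondrial messages fell, mt-Nd6 by 1.01 on the log2 scale, mt-Nd4l by 0.67 and mt-Nd3 by 0.44 (camera adjusted p = 0.0123, adjusted p = 0.326 with an estimated correlation), and mt-Nd4l and mt-Nd3 shared 98.8% and 98% of their words with other genes. Endothelial markers counted 0 that rose and 5 that fell of 10, Pecam1 (-0.72) and Flt1 (-1.14) included, the same over the list alone (camera adjusted p = 0.0123, adjusted p = 0.241 with an estimated correlation).

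Several protein folding genes fell in TGH too. The unfolded protein response counted 0 that rose and 14 that fell of 18, Dnajb9 (-0.84, log2) and Canx (-0.72) among them, with 0 and 15 when adjusted over the list alone (camera adjusted p = 3.27e-05, adjusted p = 0.578 with an estimated correlation). Heat shock proteins counted 1 that rose, Hspb7, and 4 that fell of 16, Bag3 (-0.93) among them, with 1 and 6 when adjusted over the list alone (camera adjusted p = 0.0492, adjusted p = 0.718 with an estimated correlation). The heat shock call ended without NTG 0 (camera adjusted p = 0.0818), NTG 1 (0.0546), NTG 3 (0.0787), TGH 0 (0.101) or TGH 1 (0.0784), and TGH 2 had the highest TGH mean, 8.30 log2 CPM. Clock genes counted 1 that rose and 7 that fell of 17, Ciart (-2.12, with 11.9% shared words) and Hlf (-0.78) among them, with 1 and 9 when adjusted over the list alone (camera adjusted p = 0.0492, adjusted p = 0.574 with an estimated correlation). The clock call ended without NTG 0 (camera adjusted p = 0.0708), NTG 1 (0.0681), TGH 0 (0.0718) or TGH 1 (0.0602). Inflammatory genes counted 1 that rose and 5 that fell of 11, with 1 and 8 when adjusted over the list alone, and were not called (camera adjusted p = 0.071). The median, the mean and the camera direction differed in sign for Nrf2 partners, calcium handling, glycolysis, autophagy and interferon genes, none of them called. Called members with 1 library left out were, for the unfolded protein response 9 (without TGH 0 or TGH 1) to 15 and for heat shock proteins 3 (without TGH 1) to 11 (without TGL 2). Over fits without 1 library the called members were, for clock genes 2 (without TGH 1) to 11 and for inflammatory genes 2 (without TGH 1) to 10 (without TGL 2).

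In TGH against NTG, edgeR's quasi-likelihood test called 4700 of 14511 genes, 2322 that rose and 2378 that fell, 820 and 498 of them at least 2-fold. Over all tested genes, called or not, the libraries did not overlap in 5646 (38.9%), which chance gives for 5.71%, with 4343 of these called. Camera called 16 of 38 lists, 8 up and 8 down, against 1 with an estimated correlation and 22 with fry. The count of genes was 3108 without TGH 1. Without NTG 2 and TGL 2 it was 5063.

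The comparison of TGH with TGL tests whether the lines differ. Genes of glutathione synthesis were higher in TGH, Gclm 3.02-fold (log2 1.60 ± 0.16, edgeR adjusted p = 0.00014), Gsr 2.28-fold and glutathione synthetase (Gss, with 10.3% shared words) 2.13-fold. Ptgr1 was 5.52-fold higher, Nmrk2 4.19-fold, Gsta3 3.91-fold, Srxn1 3.41-fold, Blvrb 3.23-fold, Taldo1 2.65-fold, the potassium channel partner Kcnip2 2.39-fold and Txnrd1 2.32-fold. Idh1 (-0.80, log2) and Ces1d (-1.55) were lower in TGH. Keap1 was 1.36-fold higher (edgeR adjusted p = 0.00368), and Nfe2l2 had 0.54 ± 0.21 (log2 ± SE, edgeR adjusted p = 0.129, but 0.0489 without NTG 2). The neutrophil surface gene Ly6g was 8.74-fold higher, Asic2 7.22-fold, Xkr4 6.58-fold (2.72, log2, and 1.92 without TGH 2) and the light chain Myl1, with 11.7% shared words, 5.80-fold. Poln (6.75-fold) was not called without TGL 1 (edgeR adjusted p = 0.0836), TGL 2 (0.0583) or TGH 1 (0.0784). Lower in TGH were Igsf23 (-4.24, log2), Lgi1 (-3.76), Meig1 (-3.63) and Tac1, with 3 and 54 counts, 24.6 times lower with a 95% exact interval of 7.99 to 123. In the same order these 4 genes had -3.56, -3.16, -2.97 and -3.78 without TGH 1, and -5.79, -6.89, -4.86 and -5.28 without TGH 2. Tac1 had -4.42 with all libraries and -3.81 without TGL 1. C1s1, with 2 and 192 counts, 131 times lower with 35.9 to 1092, was not called without TGL 1 (edgeR adjusted p = 0.0501) or TGH 1 (0.0641), where it had -6.16 and -6.13 (log2) against -6.76 with all libraries and -7.34 without TGL 0, and stood at 0.138, 15.0 and 11.8 CPM in the 3 TGL libraries.

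Of 11 glutathione synthesis genes 5 were higher and 0 lower in TGH than in TGL, with 7 and 0 when adjusted over the list alone (camera adjusted p = 5.4e-07, adjusted p = 0.0216 with an estimated correlation). Glutathione S-transferases counted 9 and 1 of 21, with 10 and 3 when adjusted over the list alone (camera adjusted p = 4.98e-06, adjusted p = 0.145 with an estimated correlation). Thioredoxin genes counted 6 and 0 of 15, with 8 and 0 over the list alone (camera adjusted p = 0.000189, adjusted p = 0.145 with an estimated correlation). Quinone and carbonyl genes counted 8 and 1 of 19, with 10 and 1 over the list alone (camera adjusted p = 5.08e-06, adjusted p = 0.145 with an estimated correlation). Haem and iron genes counted 2 and 0 of 12, with 3 and 0 over the list alone (camera adjusted p = 0.0261, adjusted p = 0.274 with an estimated correlation), a call lost without TGH 0 (camera adjusted p = 0.0875). Macrophage markers counted 3 and 0 of 10, with Lyz2 (1.75-fold) and C1qc (1.48-fold), and 6 and 0 over the list alone (camera adjusted p = 6.1e-05, adjusted p = 0.341 with an estimated correlation). Interferon genes counted 1 and 0 of 17, the same over the list alone (camera adjusted p = 0.00903, adjusted p = 0.632 with an estimated correlation), a call lost without TGH 0 (camera adjusted p = 0.407), whose list mean was 4.25 log2 CPM against 3.57 and 3.33 in TGH 1 and TGH 2. Without 1 library at a time the called members ran, for glutathione synthesis 3 (without TGL 0, TGL 1 or TGH 1) to 6 and for thioredoxin genes 3 (without TGL 1 or TGL 2) to 7. When 1 library was left out the called members were, for quinone and carbonyl genes 5 (without TGL 2) to 10 and for haem and iron genes 1 (without TGL 2) to 3. With 1 library left out the called members numbered, for macrophage markers 2 to 5 (without TGL 0) and for interferon genes 0 (without TGL 0) to 3 (without TGH 2).

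Lower in TGH than in TGL were 5 of 14 sarcomere genes, Tnni3 (-0.57, log2), Myl3 (-0.56) and Cmya5 (-0.80) among them, with 0 higher and 10 lower when adjusted over the list alone (camera adjusted p = 9.53e-06, adjusted p = 0.062 with an estimated correlation). Oxidative phosphorylation counted 0 higher and 5 lower of 29, Cox6a2 (-0.61) and Cox8b (-0.62) among them, with 0 and 7 over the list alone (camera adjusted p = 0.0115, adjusted p = 0.573 with an estimated correlation, and 0.105 by camera without TGH 0). Fatty acid oxidation counted 0 and 2 of 24, Hadha (-0.42) among them, the same over the list alone (camera adjusted p = 0.0359, adjusted p = 0.731 with an estimated correlation), a call lost without TGL 0 (camera adjusted p = 0.0579), TGL 2 (0.0606) or TGH 2 (0.62). Mitochondrial messages counted 0 and 1 of 3, mt-Nd6 (-0.89), with 0 and 3 over the list alone (camera adjusted p = 0.00208, adjusted p = 0.274 with an estimated correlation). Endothelial markers counted 0 and 2 of 10, the same over the list alone (camera adjusted p = 0.0115, adjusted p = 0.274 with an estimated correlation). Leaving out 1 library gave called members, for oxidative phosphorylation 3 (without TGL 0 or TGL 1) to 5 and for fatty acid oxidation 1 (without NTG 0, NTG 1, NTG 3, TGL 0, TGL 1, TGL 2, TGH 1 or TGH 2) to 3. Called members with 1 library left out were, for endothelial markers 0 (without TGL 1) to 2.

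The unfolded protein response was called lower (median -0.34, camera adjusted p = 0.0124, adjusted p = 0.731 with an estimated correlation) with 0 of 18 members called by edgeR, 0 by DESeq2 and 3 lower at an unadjusted edgeR p under 0.05. That call ended without TGL 2 (camera adjusted p = 0.507), TGH 0 (0.0875) or TGH 1 (0.0829). Clock genes counted 0 and 1 of 17, with 1 and 2 over the list alone (camera adjusted p = 0.0399, adjusted p = 0.533 with an estimated correlation), a call lost without NTG 2 (camera adjusted p = 0.0552), TGL 2 (0.193), TGH 0 (0.0875) or TGH 1 (0.088). Skeletal muscle markers counted 0 and 2 of 3, the same over the list alone (camera adjusted p = 0.0292, adjusted p = 0.404 with an estimated correlation), a call lost without TGL 2 (camera adjusted p = 0.0822) or TGH 1 (0.0613), with means of 4.42, 4.68 and 5.10 log2 CPM in TGL and 4.12, 3.23 and 3.63 in TGH. The median, the mean and the camera direction differed in sign for calcium handling, glycolysis, the integrated stress response and immediate early genes, none of them called. Over fits without 1 library the called members were, for the unfolded protein response 0 to 1 (without TGL 0) and for clock genes 0 (without TGL 1, TGL 2 or TGH 1) to 3 (without NTG 3). Without 1 library at a time the called members ran, for skeletal muscle markers 0 (without TGL 1, TGL 2, TGH 1 or TGH 2) to 2.

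In TGH against TGL, edgeR's quasi-likelihood test called 1399 of 14511 genes, 803 higher and 596 lower in TGH, 289 and 167 of them at least 2-fold. Over all tested genes, called or not, the libraries did not overlap in 4122 (28.4%), which chance gives for 10%, with 1389 of these called. Camera called 15 of 38 lists, 7 up and 8 down, against 1 with an estimated correlation and 14 with fry. The count of genes was 803 without TGL 1 and 730 without TGH 1. Without NTG 2 and TGL 2 it was 1266.

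**Figure D3:**
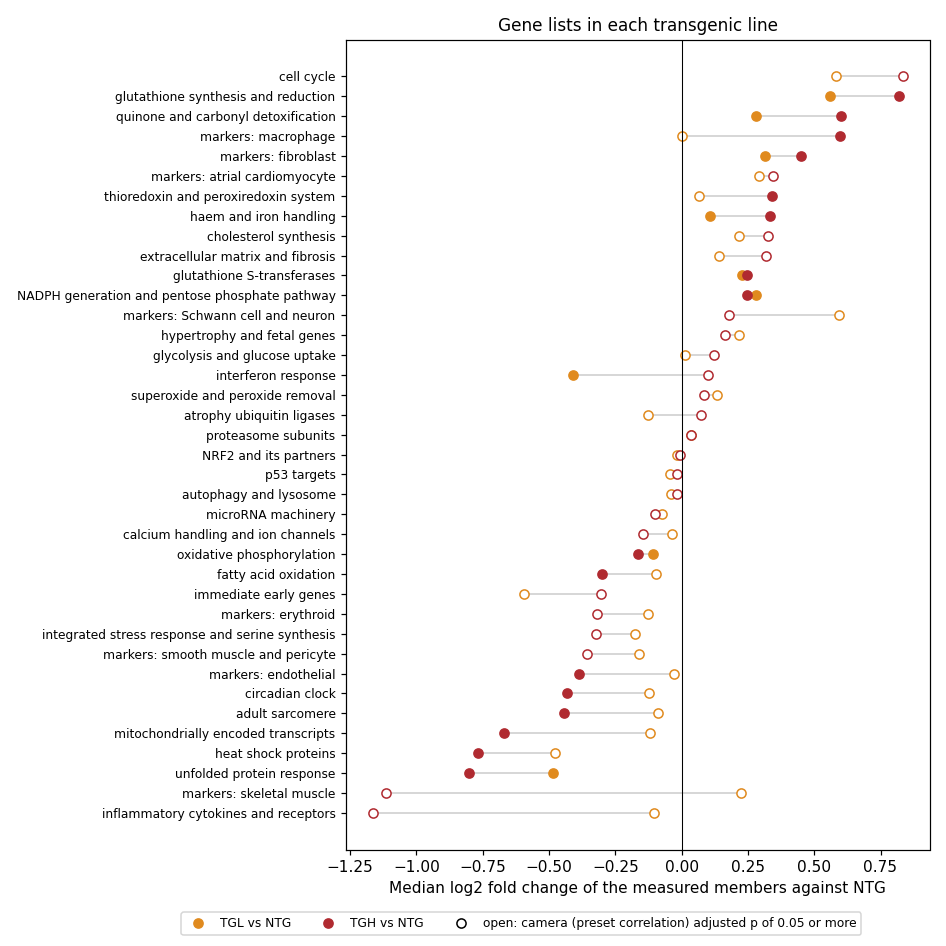
Median log2 fold change of the measured members of 38 gene lists in TGL (orange) and TGH (red) against NTG, with filled points for lists called by camera with a preset correlation. Glutathione synthesis and reduction was called in both lines, with 5 of 11 members that rose in TGL and 9 in TGH.

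The responses of the lines overlapped. Of 602 genes that rose in TGL, 556 (92.4%) rose in TGH, and of 311 that fell 274 (88.1%) fell in TGH. Independent lists would share 96.3 and 51.0, but both lists were called against the same 4 NTG libraries. With each line fitted alone against 2 NTG libraries that the other did not use, 6 choices of controls gave 122 to 383 genes that rose in both, where independent lists share 15.7 to 48.5. The genes that fell in both numbered 10 to 131, where independent lists share 2.51 to 22.3. The shared part was 63.9 to 96.8% of the genes that rose in TGL and 43.8 to 71.9% of those that fell. Enpep and Plekhm3, chosen after their values were seen, were the 2 of 832 genes called in both lines with opposite directions. Enpep rose by 0.48 ± 0.11 in TGL (log2 ± SE, edgeR adjusted p = 0.0241) and fell by 0.42 in TGH (edgeR adjusted p = 0.0154), and Plekhm3 fell by 0.57 in TGL (edgeR adjusted p = 0.00744) and had 0.375 in TGH (edgeR adjusted p = 0.011). Across 14511 genes, which are not independent replicates, the log2 fold changes of TGL and TGH correlated with r = 0.845 and a covariance of 0.441. Simulated unchanged groups that share the same controls gave r = 0.422 and a covariance of 0.0227 on average over 20 simulations, beside 0.811 and 0.285 for the data computed the same way, from mean log2 CPM. With the controls split so that no NTG library served both lines, r was 0.684, 0.715 and 0.696 and the covariance 0.258, 0.266 and 0.262. Of the 1332 genes that rose in TG, 1177 (88.4%) lay further from NTG in TGH than in TGL, with medians of 0.566 in TGL and 0.95 in TGH (log2). Of the 1145 that fell, 993 (86.7%) did, with medians of -0.401 and -0.619.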

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

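Libraries were compared within NTG and within TG by the gap of the furthest library to its neighbour, and 27 of 384 such tests (7.03%) stood apart, where chance flags about 1 in 20. Of these, 2 rest on a single read (Atp1b4 and Ly6g) and show no difference between libraries. By library the 27 were 8 in NTG 2, 7 in TGL 2, 7 in TGH 2, 2 in TGL 1 and 1 each in NTG 0, NTG 3 and TGH 1. The tests of other splits below were chosen after the counts of genes had been seen.

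NTG 2 stood apart in Timp4 (71.3 CPM, others 44.0 to 45.1), Ly75 (4.06, others 1.60 to 1.94), Nppb (628, others 78.1 to 159), Acot2 (38.7, others 67.3 to 70.4, with 27.7% shared words), Poln (5.97, others 2.29 to 2.67), Myl1 (66.9, others 36.1 to 37.5) and Kcnip2 (271, others 224 to 230). NTG 0 did in Cox6a2 (1790, others 1590 to 1600) in the same test. The values of Atp1b4 in NTG 2 (0.119 CPM, 0 in the others) and of Ly6g in NTG 3 (0.114, 0 in the others) lie under the limit of 3 counts and are not read as standing apart.

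TGL 2 stood apart from the other TG libraries in Ppara (58.2 CPM, others 28.0 to 33.7), Herpud1 (275, others 144 to 177), Bag3 (459, others 213 to 272), Osmr (55.3, others 15.5 to 22.3), Flt1 (231, others 88.6 to 140), Ciart (16.0, others 1.64 to 6.93) and the mean of the inflammatory list (4.18 log2 CPM, others 2.33 to 2.55). TGL 1 did in Nppa (893, others 293 to 378) and Tchhl1 (5.17, others 2.05 to 3.17), and TGH 1 in Prdx6 (1830, others 477 to 714). TGH 2 did in Nppb (656, others 261 to 394), Lox (1.94, others 3.13 to 3.73), Pi16 (117, others 71.4 to 87.4) and Xkr4 (12.7, others 0.951 to 5.27). TGH 2 also did in the mean log2 CPM of calcium handling (7.52, others 7.62 to 7.67), fatty acid oxidation (7.69, others 8.16 to 8.23) and proteasome genes (6.68, others 6.56 to 6.60).

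The lines differed from each other in 1399 genes by edgeR's test of TGH against TGL. Enpep (-0.90, log2, edgeR adjusted p = 0.000749) and Plekhm3 (0.95, edgeR adjusted p = 0.000299) had opposite directions against NTG and were chosen after their values were seen.

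Other splits of the libraries were counted with edgeR. For TG against NTG 2 of 100 splits drawn from 210, the real one included, gave as many genes, a share under 0.05. The real split gave 2477 genes. The highest other split gave 2785, set TGH and TGL 0 against the rest and so follows the structure of the lines. For TGL against NTG 1 of 35 splits gave as many genes (792, highest other 37) and for TGH against NTG 1 of 35 (4568, highest other 61), fitted with the 2 groups alone. A share of 1 in 35 is under 0.05 but is the smallest that these splits allow. For TGH against TGL 1 of 10 splits gave as many, with 1145 genes and at most 1 in another, and 10 splits are too few for a share under 0.05. Splits cannot tell the transgene from another difference that runs along with the groups.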

How the results depend on the processing

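Leaving out NTG 2 with TGL 2, the heat shock covariate, the groups' overlap over all tested genes, and the list tests of TGL and of TGH against NTG were chosen after seeing the data. Ranges below leave out 1 library at a time, and the cause of a change was not tested unless named.

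Genes changed, TG against NTG, numbered 2477, with DESeq2 2899, RLE scaling 2463, no filter 2374 and a stricter filter 2469. They were 1182 (without NTG 1) to 3551 (without TGL 2), 3727 with 3 groups, 659 at an adjusted p under 0.01, 3917 under 0.1, 666 at least 2-fold and 552 with the heat shock covariate, which runs along with the groups. TGL against NTG gave 457 (without TGL 0) to 1399 (without TGL 2) around 913, and 1666 without NTG 2 and TGL 2. TGH against NTG gave 3108 (without TGH 1) to 5017 (without TGL 2) around 4700. TGH against TGL gave 730 (without TGH 1) to 1599 (without NTG 2) around 1399. With the replicate number as a block TG against NTG gave 1338 genes, TGL against NTG 1063, TGH against NTG 4320 and TGH against TGL 1277. The numbers were not taken as pairs, since not every same-number correlation was over 0.1: same-number correlations of deviations were -0.0417, -0.0525 and -0.00428 between NTG and TGL, and 0.00452, -0.036 and 0.0146 between NTG and TGH. Between TGL and TGH they were 0.15, 0.0625 and 0.335, where other numbers gave -0.26 to 0.152. TGL 2 with TGH 2 was the highest of all pairs, while TGL 0 correlated best with TGH 1 (0.152), and pairing of the 2 lines is not excluded. On the third principal component (8.9% of the variance) NTG 2, TGL 2 and TGH 2 stood at 17.46, 33.01 and 13.27. The other libraries lay between -13.55 and -0.4425 there. A batch shared by the libraries numbered 2 is therefore not excluded, though NTG 2 correlated with TGL 2 and TGH 2 at only -0.00428 and 0.0146.

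Lists called numbered 15 to 20 around 18 in TG against NTG, 9 to 15 around 9 in TGL against NTG (19 without NTG 2 and TGL 2), 14 to 20 around 16 in TGH against NTG and 10 to 18 around 15 in TGH against TGL. With an estimated correlation they were 0 (3 at an unadjusted p under 0.05), 2, 1 and 1, and with fry 13, 11, 22 and 14. Whichever 1 library was left out, 12 of 18, 8 of 9, 12 of 16 and 8 of 15 lists were kept.

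Nfe2l2 in TG against NTG differed by 0.38 to 0.68 (log2) in the permutation test. In edgeR it was past the threshold without TGL 1 (edgeR adjusted p = 0.0412). In TGL against NTG it had -0.013 without NTG 2 and TGL 2. Hmox1 in TG against NTG reversed to -0.21 with the block and -0.11 without NTG 2 and TGL 2. Myh7 ranged from -0.20 (without TGL 2) to 0.17 (without NTG 2), with 0.03 without TGH 1, and reversed to 0.0057 with the block and 0.038 without NTG 2 and TGL 2. Of the named genes called, 70 of 112 in TG against NTG kept the call without any 1 library, 24 of 35 in TGL, 54 of 54 in TGH and 37 of 48 in TGH against TGL. With the replicate block 78 of 112, 31 of 35, 54 of 54 and 47 of 48 kept it, and with the heat shock covariate 50 of 112, 29 of 35, 53 of 54 and 48 of 48. Over all named genes, leaving out 1 library kept direction and side of the threshold in 2275 fits, ended a call in 264, added 3 and reversed 2. DESeq2 kept direction and side in all 255. The correlation of the lines' fold changes, 0.845, was 0.684, 0.715 and 0.696 with split controls.

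A gene under 3 counts in a library lies under 0.259 to 0.436 CPM, and low genes at 0 there are not shown to be absent.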

Other observations

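The tests of a mislabelled sample, of genes flanking the clusters and of the state of the tissue, the windows along the chromosomes, the marker sums by library and the genes named here were chosen after the results had been seen.

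Some RNAs of the mitochondrial genome beyond the messages of the gene list fell in TGH and 1 rose. The ribosomal mt-Rnr2 fell by 1.79 (log2, edgeR adjusted p = 0.00276) and mt-Rnr1 by 1.45 (edgeR adjusted p = 0.000658), and so did the transfer RNA genes mt-Te (-1.20, edgeR adjusted p = 2.02e-06) and mt-Tq (-2.13, edgeR adjusted p = 8.56e-05). The transfer RNA gene mt-Ts2 rose (0.47, edgeR adjusted p = 0.0391), and mt-Tl2 (0.45), mt-Th (0.21) and mt-Tt (0.05) had positive values that did not pass. Of 26 mitochondrial genes tested, 13 fell at least 2-fold (hypergeometric adjusted p = 9.43e-06, Benjamini-Hochberg over 535 windows of 5 Mb). That test takes genes as independent draws, so its p does not measure the spread between mice. mt-Rnr2 stood at 26480, 23310, 11980 and 20030 CPM in NTG, 7597, 6415 and 18490 in TGL and 5542, 5388 and 6780 in TGH, so NTG 2 and TGL 2 lay nearer to the other group here too.

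Some genes were on in some libraries of a group and off in others: 38 in NTG, 28 in TGL and 24 in TGH had at least 3 CPM in 1 library and were more than 10 times lower in another, furthest in NTG 2 for 27 of the 38, in TGL 2 for 18 of the 28 and in TGH 2 for 12 of the 24. Aqp6 had 0.134, 0.104, 75.5 and 0 CPM in NTG, and Dnajc28 86.3, 90.6, 2.99 and 87.4. In TGL these genes had 0, 0.272 and 0, and 39.8, 79.2 and 68.1, unlike NTG 2. In other genes NTG 2 stood near TGL. Baiap2l1 had 24, 24.7, 224 and 20.6 CPM in NTG, 165, 216 and 203 in TGL and 18.6, 124 and 147 in TGH. Fgf7 had 3.47, 0.932, 11.1 and 2.4 in NTG, 11.3, 10.2 and 11 in TGL and 2.69, 3.37 and 2.37 in TGH. A mislabelled NTG 2 is argued against, since its mean of the glutathione synthesis list was 0.476 log2 CPM under the lowest TG library, where the other NTG libraries spanned 0.0783. Variants of the strain and RNA of liver or kidney cannot be told apart from other causes. The 200 genes furthest in NTG 2 made 5 neighbouring pairs (random median 2, highest 9, permutation p = 0.119), a count that cannot see a variant at a lone gene. Ifi202b, near Ifi205 on chromosome 1, stood at 20.3 CPM in NTG 2, 8.7, 6.8 and 20.9 in TGL and 8.64 in TGH 1. It had 0 to 0.117 in the other libraries. Liver markers were 2.64 times the other NTG libraries over 7 genes (12.4 against 4.69 CPM). In NTG 2 Ahsg had 9.31 CPM, Serpina1b 1.91, Serpina1a 0.836, Apoa2 0.239, Apob 0.119, and Apoa1 and Ttr 0. Apoa2 was higher in the other NTG libraries (0.343 to 1.07). Kidney markers, 10 genes, were not highest in NTG 2 (1.91 CPM) but summed to 8.11 in NTG 3, 7.99 in TGL 2 and 3.78 in TGH 2, with 0.828 to 2.85 in the other 6 libraries, and Kap had 18.7 CPM in NTG 3, 26.9 in TGL 2 and 7.45 in TGH 2, with 0 to 0.597 in the other 7, so RNA of kidney stays open there, and no biological explanation was tested.

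Clusters of multi-copy genes rose on chromosomes 14 and 2. On chromosome 14, from 3049285 to 7568566, 28 of 31 genes rose in TGL and 31 in TGH (medians 3.32 and 4.69, log2), and on chromosome 2, from 175010241 to 177957297, 5 and 33 of 43 (medians 0.287 and 1.21). Reads shared between copies may set these values, since the median gene shared 86.5% of its 50-base words with another annotated gene, so the copies are not separate measurements. A strain variant near the clusters cannot be told apart from this: 12.5% of flanking genes (8 of 64, 95% interval 5.55 to 23.2) changed at least 2-fold in TGH, against 8.89% of all genes. A response of the copies to the transgene stays open as well, untested.

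The fall of the unfolded protein response and heat shock lists varied within groups, and across 10 libraries the deviations of these lists from their group means correlated with r = 0.981 (permutation p = 0.0047, adjusted p = 0.0235 by Benjamini-Hochberg over 5 relations, rho 0.939, r = 0.965 without the 2 furthest libraries). A relation of the unfolded protein response list to log2 total count was not found within groups (r = -0.204, permutation p = 0.584). That r leaves out the differences between groups, and 10 libraries are too few to exclude a relation. A difference in library size therefore stays open. A state of the tissue at collection cannot be told apart from other causes: the relation to immediate early genes had r = 0.565 (permutation p = 0.325, rho 0.527, r = 0.248 without the 2 furthest libraries), and 10 libraries are too few to settle it. The relation to the clock list had r = 0.847 (permutation p = 0.03, adjusted p = 0.075 by Benjamini-Hochberg, r = 0.637 without the 2 furthest) and to the glutathione list r = 0.0227. An effect of the transgene on protein folding stays open as well.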
